A study of Klebsormidium nitens with 6 samples.

How the data were processed

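RNA was sequenced from Klebsormidium nitens, a filamentous streptophyte alga, after incubation in liquid medium. The medium held no added oxylipin (mock) or 25 µM OPDA (12-oxo-phytodienoic acid). OPDA is a reactive oxylipin and the precursor of jasmonate in vascular plants. Algae had been grown on plates before the incubation, which lasted 2 hours, per the labels' protocols. Total RNA was extracted with a DNase step and the libraries were made by a sequencing provider, per the labels' protocols. There were 3 mock libraries (replicates 1, 2 and 3) and 3 OPDA libraries (replicates 1, 2 and 4), with groups and numbers taken from the sample titles. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

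Each library had a table of raw read counts per gene that the authors deposited, with 17153 gene IDs and whole numbers only. Trim Galore, HISAT2, HTSeq and DESeq2 are named in the submitters' processing notes; their versions, the genome build, the counting mode and the use of strand are not given in the sources used here. Reads from overlapping, antisense or near-identical genes therefore cannot be assigned with certainty. No row for unassigned reads was present in the tables. The authors also deposited a normalized signal table of counts divided by a size factor. In each library every value of that table equalled the raw count divided by 1 constant, between 0.962 and 1.043, which matched the median-of-ratios size factor of the same 17152 genes. All values times that constant came out whole within 1e-06. The table left out 1 gene, the first row of the count files. It was used for this check only, because a count test on it would repeat the test on the raw counts of 17152 genes. It is represented among the alternatives by the median-of-ratios scaling.

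The files give gene IDs without names or descriptions. Of the 17153 IDs, 16048 had the digits of a locus tag in the gene table of assembly ASM70883v1, and each scaffold number of the files corresponded to 1 scaffold of that table. That table gave a symbol other than the locus tag for 151 genes, none of which matched an ID of the files, and it gave no product descriptions. The lists of heat shock, detoxification, photosynthesis, cell wall and other genes that had been fixed as text patterns before the data were examined, and the lists for flagellar and gamete genes, could not be matched to any ID and were not tested. No coordinates are given because the build behind the counts is not stated. The table was used for locus tags and for which genes are neighbours.

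Library totals ranged from 23693021 to 24169072 counts. CPM printed here (counts relative to the scaled library total) were computed with TMM factors, which ranged from 0.965 to 1.036. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the raw counts of all 6 libraries, with robust estimation, no covariate and Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was the threshold. Genes were kept by edgeR's filterByExpr with its default minimum count of 10, which left 11752 genes. Standard errors of log2 fold changes were the fold change divided by the square root of the F statistic. The test was tried on simulated data drawn from the mock means and dispersions of 11752 genes, with 200 genes changed: 99 of 100 genes changed 2-fold and 100 of 100 changed 4-fold were recovered, and 20 of the 219 calls were false. The false share was thus above the nominal 5% in that simulation. All changed genes had an expected count of at least 20, and no change under 2-fold was simulated. Neither the recovery nor the false share therefore carries over to the smaller changes that make up most calls in the data.

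The rule for named genes was fixed before the data were examined. It took, when no descriptions were at hand, the 2 genes with the largest and the 2 with the smallest log2 fold change among genes past the threshold, with a mean of at least 5 CPM and with no overlap between the 3 OPDA and the 3 mock values. The alternatives were median-of-ratios or total-count scaling, DESeq2 1.42.0 (Wald test), limma-voom, no or a stricter filter on low counts (at least 10 CPM in at least 3 libraries), estimation that was not robust, the replicate number as a block, and leaving out each library. A test against a 1.5-fold change (edgeR's glmTreat) was added after the data had been seen. Neighbouring genes were compared with 100000 permutations of the fold changes within deciles of mean CPM (Python 3.11.15, numpy 2.4.6, scipy 1.17.1), after a check on simulated values. Counting error depends on the counts of each gene and is not small where these are low. The sequencing reads carried no stated molecular identifiers. Precision is given as the spread between libraries, which includes counting error.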

Results

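The data were 6 gene count tables from K. nitens, 3 from mock-treated algae and 3 from algae exposed to 25 µM OPDA for 2 hours. The mock libraries held 23963595, 24169072 and 23981871 counts (replicates 1, 2 and 3) and the OPDA libraries 23899396, 23989299 and 23693021 counts (replicates 1, 2 and 4). A mean of 12576 ± 61.3 genes (SD, n = 3) had at least 1 count in mock and 12596 ± 47.5 (SD, n = 3) in OPDA. Of the 17153 gene IDs, 3753 had no count in any library. The 6 pairs of libraries from the same group had correlations of log2 CPM across genes between 0.993 and 0.997, against 0.940 to 0.955 for the 9 pairs from different groups. Genes are not independent replicates, so these correlations carry no test. No library pair was a duplicate: the chi-square of counts per degree of freedom was between 6.11 and 17.2 within groups, where sampling noise alone would give about 1. In a principal component analysis of log2 CPM, the first component held 85.0% of the variance and separated the groups. Mock libraries lay at -37.3, -34.0 and -31.6 on it and OPDA libraries at 33.0, 34.4 and 35.6. The second component held 5.30% and set mock replicate 1 apart, at 15.65. The other libraries lay between -9.395 and 3.415 on that component.

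The comparison of OPDA with mock asks how the transcriptome of this alga responds to a reactive oxylipin. The series title sets this treatment in the context of responses that do not need COI1 and of tolerance to heat. COI1 is the jasmonate receptor of vascular plants. Transcripts of 6348 of the 11752 genes tested (54.0%) differed between the groups, 3115 of them higher and 3233 lower in OPDA (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most of these changes were small: the median absolute change of the genes past the threshold was 1.35-fold, and 1024 genes had a fitted change of at least 2-fold, 413 higher and 611 lower. Large inductions outnumbered large reductions, with 54 genes at least 8-fold higher and 15 at least 8-fold lower. Without mock replicate 1 these counts were 50 and 8. The balance of direction among all genes past the threshold depended on the scaling of the libraries: 49.1% of them were higher in OPDA with TMM factors and 35.7% with total counts alone, 2232 higher against 4027 lower. The 3 OPDA values did not overlap the 3 mock values in 62.5% of the tested genes, where chance gives 10%.

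**Figure D1:**
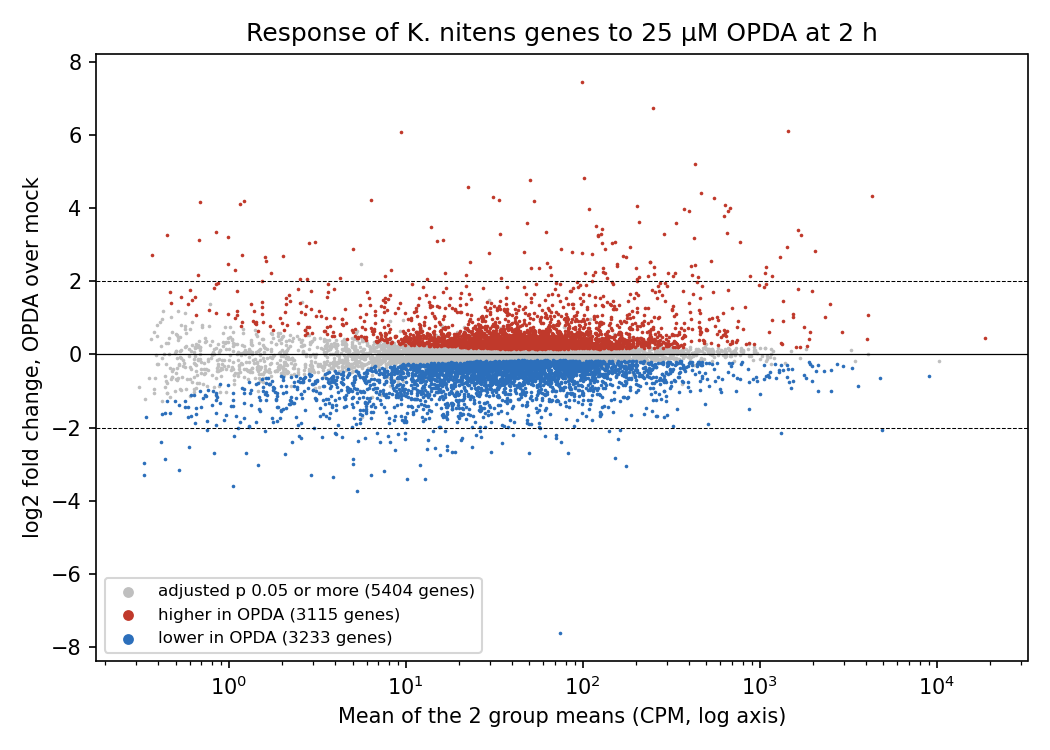
Log2 fold change of OPDA over mock (vertical axis) against the mean of both group means in CPM (horizontal log axis) for the 11752 tested genes, each point 1 gene; dashed lines mark a 4-fold change. Red points are the 3115 genes higher and blue points the 3233 genes lower in OPDA at an adjusted p under 0.05, and grey points did not pass; most coloured points lie between the dashed lines.

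Among genes past the threshold with a mean of at least 5 CPM and non-overlapping groups, the most induced was kfl00616_0050_v1.1 (locus tag KFL_006160050). It had 1.12 ± 0.674 CPM in mock and 198 ± 33.0 CPM in OPDA (SD, n = 3 each), a ratio of means of 176 and a log2 fold change of 7.46 ± 0.31 (SE; edgeR adjusted p = 6.86e-06). Its raw counts were 46, 22 and 15 in the mock libraries and 4349, 5472 and 3967 in the OPDA libraries. Without mock replicate 1, which held 46 of these mock counts, the log2 fold change was 8.05. The next was kfl00896_0010_v1.1 (KFL_008960010), which rose from 4.60 ± 1.25 to 494 ± 88.2 CPM (SD, n = 3 each), with a log2 fold change of 6.74 ± 0.24 (SE; edgeR adjusted p = 6.51e-07). In the other direction, kfl00033_0110_v1.1 (KFL_000330110) went from 149 ± 44.7 CPM in mock to 0.747 ± 0.215 CPM in OPDA (SD, n = 3 each), with a log2 fold change of -7.63 ± 0.39 (SE; edgeR adjusted p = 4.55e-05). Its raw counts were 4860, 3309 and 2834 in mock and 18, 22 and 12 in OPDA. The gene kfl00241_0010_v1.1 (KFL_002410010) went from 9.86 ± 0.915 to 0.732 ± 0.110 CPM (SD, n = 3 each), with a log2 fold change of -3.74 ± 0.19 (SE; edgeR adjusted p = 5.02e-09). The gene table used here gives no product for any of these 4 genes.

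**Figure D2:**
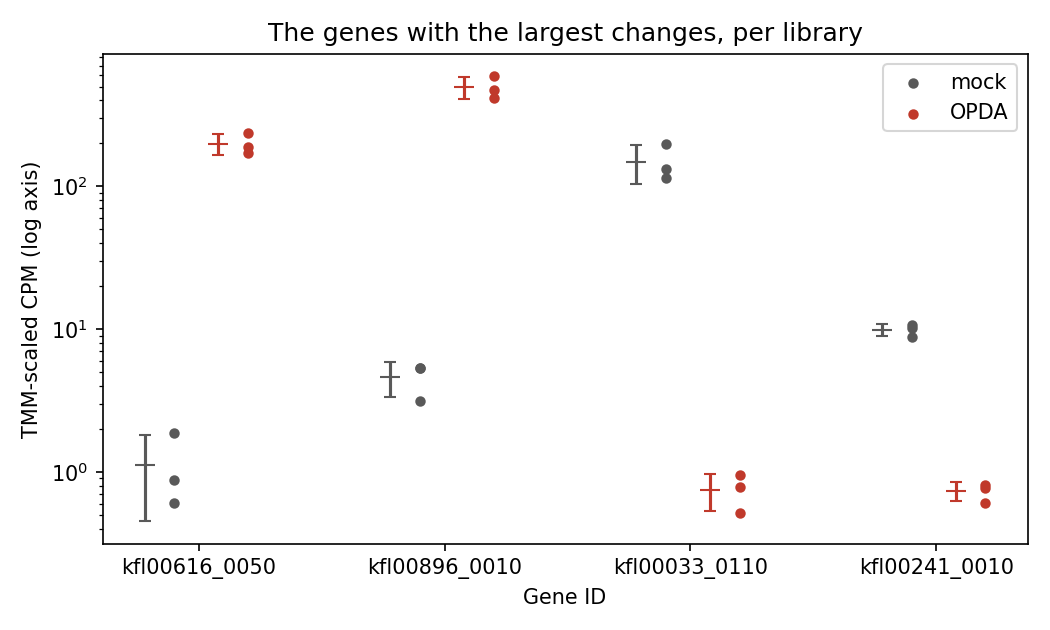
TMM-scaled CPM (vertical log axis) of the 4 named genes, as points for each library. Bars show the mean and SD (n = 3) of mock (grey) and OPDA (red). These are the 2 largest rises and 2 largest falls under the rule for named genes (mean of at least 5 CPM, no overlap between groups). The kfl00616_0050 values lie under 2 CPM in mock and between 171 and 235 CPM in OPDA, and those of kfl00033_0110 lie between 114 and 199 CPM in mock and under 1 CPM in OPDA.

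Induced and reduced genes differed in their numbers by the size of the change. Between 2-fold and 4-fold, 290 genes were higher and 535 lower in OPDA. Between 4-fold and 8-fold the counts were 69 higher and 61 lower, and at 16-fold or more 20 genes were higher and 1 was lower. The single gene lower by at least 16-fold was kfl00033_0110_v1.1. These are counts of fitted changes among genes past the edgeR threshold, and the order of higher and lower within the 2-fold to 4-fold class and at 8-fold or more did not turn under any of the 15 alternatives. Between 4-fold and 8-fold the order was not settled: it turned with total-count scaling (69 higher and 77 lower), without OPDA replicate 2 (71 and 85) and without mock replicate 2 (72 and 73). Over these alternatives the 2-fold to 4-fold class held 224 to 313 higher and 373 to 626 lower genes, and the class of 8-fold or more held 44 to 64 higher and 6 to 21 lower genes.

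**Figure D3:**
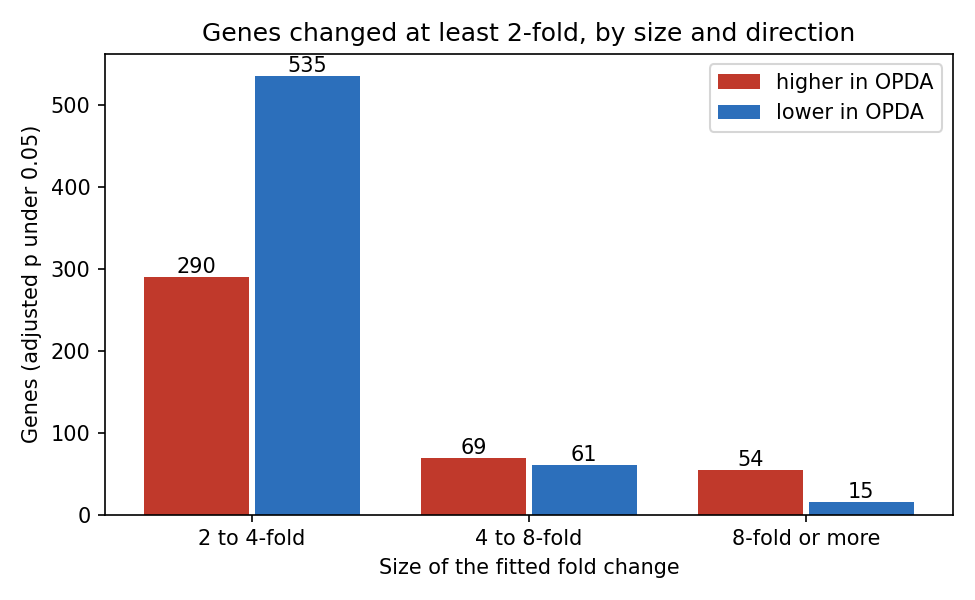
Numbers of genes (vertical axis) past an adjusted p of 0.05 by the size of the fitted fold change (horizontal axis), higher (red) or lower (blue) in OPDA than in mock. Genes lower in OPDA are more numerous in the class of 2-fold to 4-fold (535 against 290) and genes higher in OPDA in the class of 8-fold or more (54 against 15).

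The 123 genes that rose at least 4-fold were mostly not silent in mock. In mock, 22 of them had a mean under 1 CPM, 23 had 1 to 10 CPM, 58 had 10 to 100 CPM and 20 had at least 100 CPM. In OPDA, 78 of the 123 reached at least 100 CPM. Their median was 23.3 CPM in mock and 217 CPM in OPDA. Together they took 0.791% ± 0.040 of all counts in mock and 6.22% ± 0.281 in OPDA (SD, n = 3 each). Both the direction and much of the size of this difference follow from how the genes were picked, so it describes the group and tests nothing. The 5 most abundant of them held 32.5% of the group's CPM in OPDA. All 123 had 3 OPDA values above all 3 mock values, and their median SD of log2 CPM was 0.196 between mock libraries and 0.134 between OPDA libraries.

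The 76 genes that fell at least 4-fold had a median of 16.2 CPM in mock and 2.62 CPM in OPDA. In mock, 13 of them had at least 100 CPM, and in OPDA 21 of them had a mean under 1 CPM. They took 1.37% ± 0.020 of all counts in mock and 0.288% ± 0.043 in OPDA (SD, n = 3 each), again a difference largely set by the choice of genes. A single gene, kfl00030_0090_v1.1, named after its values were seen, held 59.4% of the group's CPM in mock. It went from 7921 ± 501 CPM to 1900 ± 356 CPM (SD, n = 3 each), with a log2 fold change of -2.06 ± 0.13 (SE; edgeR adjusted p = 3.23e-07), close to the 4-fold limit. Without this gene the other 75 took 0.556% ± 0.053 of counts in mock and 0.104% ± 0.012 in OPDA (SD, n = 3 each). Without OPDA replicate 4 its log2 fold change was -1.91, so it left the group, and the 83 genes then at least 4-fold lower took 0.622% of counts in mock and 0.124% in OPDA. No gene past the threshold was without counts in all libraries of either group. Even 1 count in 1 library meets this, so means under 1 CPM may still lie near the detection limit.

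Among the 2938 tested genes with the highest mean over all 6 libraries (at least 77.3 CPM), 955 were higher and 795 lower in OPDA, and at least 2-fold changes numbered 179 higher and 87 lower. Among the 2938 genes with the lowest mean (up to 18.1 CPM), 450 were higher and 917 lower, and at least 2-fold changes numbered 125 higher and 330 lower. The balance of at least 2-fold changes differed between these groups, with an odds ratio of 5.42 (95% interval 3.86 to 7.65, two-sided Fisher's exact test p = 1.06e-25). That test treats genes as independent and was chosen after the counts were seen. The OPDA values are part of the mean used for grouping, which moves rising genes up and falling genes down. Part of the difference between the groups was therefore set in advance. With total-count scaling the order among all calls in the abundant group turned, to 717 higher and 991 lower, while the at least 2-fold counts were 159 higher and 111 lower there and 111 higher and 380 lower in the scarce group (odds ratio 4.89). Grouped by the mean of log2 CPM, the at least 2-fold counts were 160 higher and 77 lower in the most abundant 2938 genes. In the least abundant 2938 they were 136 higher and 356 lower. A rise and a fall of one size shift that mean by like amounts, but the OPDA values still enter it. At 4-fold, the ratio of rising to falling genes was 1.62 over all tested genes and 1.66 among those with at least 10 CPM in mock. How far the link to abundance holds by mock level at 2-fold was not tested. The median SD of log2 CPM between libraries of a group was 0.148 in the least abundant group and 0.085 in the most abundant one, so a change of a given size was measured less precisely for scarce transcripts.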

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

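Of 120 counts of genes recomputed under 15 alternatives, 116 stayed within 1.5 times the value in the report. The stricter filter on low counts gave 48 genes lower at least 4-fold in place of 76, with fewer genes tested. The test against a 1.5-fold change, chosen after the data had been seen, called 1238 genes, 488 higher and 750 lower, since it asks for a larger change by construction. All 59 values of the 4 named genes kept their direction and an adjusted p under 0.05, and kfl00241_0010_v1.1 was not tested under the stricter filter. These genes were picked from the same data for their large changes, so that outcome was largely set by the choice. The log2 fold change ranged from 7.16 to 8.05 for kfl00616_0050_v1.1, with adjusted p up to 0.000166, and from -7.83 to -7.36 for kfl00033_0110_v1.1, with adjusted p up to 0.000821. DESeq2 called 5940 genes and limma-voom 6368, and they kept 5817 and 6275 of the 6348 calls in the same direction. Total-count scaling kept 5465 of them and none of the 6348 calls changed sign under any alternative that tested it. Leaving out 1 library gave 5536 to 5999 genes past the threshold. Replicate numbers 1 and 2 occur in both groups but nothing says that they mark a shared culture or day. Deviations of same-numbered libraries correlated at 0.076 and -0.0714 across genes. Both values lay within the range for mock and OPDA libraries with different numbers, -0.104 to 0.0827. With the replicate number as a block (replicate block), 5023 genes passed and 4859 of the 6348 calls were kept. Mock replicate 3 and OPDA replicate 4 share their number with no other library, so they add nothing to the treatment effect in that fit. It rested on replicates 1 and 2 of each group, so these counts are not a like comparison on all 6 libraries. The tests of gene lists, with their own alternatives, were not run because no ID has a description. Depth was not varied; from the least to the most abundant group of 2938 genes, 1571, 1362, 1283 and 1188 did not pass the threshold.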

Other observations

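Genes next to each other on a scaffold of assembly ASM70883v1 had more similar responses to OPDA than genes of like abundance placed at random. The tests of genes changed at least 8-fold, the ratios by log2 mean and by mock level and the reading of the correlation at a distance of 1 gene were chosen after their values had been seen. There were 9 adjacent pairs in which both genes rose at least 4-fold, against a mean of 0.981 in 100000 permutations (one-sided permutation p = 1e-05, the smallest they can give; adjusted p = 2.5e-05 over 10 tests). For pairs in which both fell at least 4-fold, 1 was seen and 0.373 were the permutation mean (p = 0.312, adjusted p = 0.329).

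Over 8870 adjacent pairs, the log2 fold changes correlated with Pearson's r = 0.162 and Spearman's rho = 0.148 (one-sided permutation p = 1e-05 each, the smallest possible; adjusted p = 2.5e-05), across genes that are not independent replicates; the upper bound of the central 95% of permutations was 0.0245. A few clusters of strongly responding genes were argued against as the whole of this, because without genes changed at least 4-fold r was still 0.156, above the permutation bound of 0.0251. The correlation of adjacent genes and its permutation bound were set in advance, but were tested on these 6 libraries only. That neighbours respond alike remains a hypothesis beyond them, and what links neighbours was not tested. Reads counted for both of a pair of overlapping or adjoining genes stay open: with 1 gene between, r was 0.0272, just over its permutation bound of 0.0228 (p = 0.00966, adjusted p = 0.0193), but a chain of alike adjacent pairs would give about the square of the adjacent value, 0.0263, so the bound set in advance could not separate the explanations. With 1 gene between, Spearman's rho was 0.0155 (adjusted p = 0.136), and the values with 2, 3 and 4 genes between, 0.0139, 0.00565 and 0.0231, did not pass adjustment (adjusted p = 0.160, 0.329 and 0.0595).

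Large inductions outnumbered large reductions while moderate changes went the other way. At 4-fold the ratio of rising to falling genes was 1.62 (95% exact binomial interval 1.21 to 2.18, which treats genes as independent). Scarce transcripts near the detection limit were argued against as the whole of this, since the ratio was 2.60 (1.76 to 3.90) among genes with a mean of at least 10 CPM over all libraries. The change itself helps to set that mean: the ratio was 2.79 (1.86 to 4.29) with the mean taken on the log2 scale and 1.66 (1.14 to 2.44) among genes with at least 10 CPM in mock. Library scaling and a single library stay open at 4-fold, because the ratio was 1.26 (0.95 to 1.67) with total-count scaling and 1.23 (0.937 to 1.62) without OPDA replicate 2. At 8-fold the ratio was 3.60, and the lowest value under the other scalings was 3 (1.67 to 5.66). Total-count scaling moved the median log2 fold change only from 0.00447 to -0.0763, so a larger shift in scaling was not tested. A single library was argued against at 8-fold: the lowest ratio with 1 left out was also 3 (1.73 to 5.44, without mock replicate 2). Without mock replicate 1 the ratio was 6.25, with 50 rising and 8 falling genes, so its size depends on that library. An effect of OPDA itself, the difference the design names, remains an untested hypothesis beyond these 6 libraries.

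Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many as 6348 genes past the threshold, and the highest count among the others was 0. With 10 splits a share under 0.05 is out of reach. Each of the other splits also placed mock and OPDA libraries together within its groups. The difference between mock and OPDA then added to the spread within groups, which works against calls. The count of 0 is therefore no measure of false calls, and the splits cannot decide how many of the 6348 calls chance would give.

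The gene IDs of the count tables fall into 3 forms that differed in how often they were detected. Of 16048 IDs with a 4-digit gene number, 3176 (19.8%) had no count in any library, against 526 of 1012 (52.0%) with a g number and 51 of 93 (54.8%) with an mRNA suffix. Each of these 93 IDs repeats the ID of another row with the suffix added; both rows had counts in 40 cases and neither in 44, and how reads were assigned between them was not tested. Undetected IDs were most frequent on scaffolds with high numbers: 13.9% of IDs on scaffolds numbered up to 500 had no count, 29.7% on those above 500 and up to 1000, and 70.7% on those above 1000.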
